A study of Oryza sativa with 24 samples.

How the data were processed

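The series compared cytokinin-treated and solvent-treated organs of rice (Oryza sativa L. cultivar Nipponbare) on a 1-colour rice array. Roots or the third leaf were cut from hydroponic seedlings and kept at 30 °C in water with either 5 µM trans-zeatin (tZ, an active cytokinin) or 0.1% dimethylsulfoxide (DMSO, the solvent) for 30 or 120 min, per the labels' protocols. The 24 arrays form 8 groups of 3, and groups were taken from the sample titles. The tissue field names root for all 24 samples, whereas titles, source names and protocols give leaf for 12 of them, so the organ was checked in the values before use. The protocol text of the root tZ 30 min samples names both incubation times, and the title was followed.

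Per the labels' protocols, total RNA was prepared with a column kit and turned into biotin-labelled cRNA. The deposited values are the authors' processed intensity, 1 linear signal per probe set and array, and the summarising algorithm, background correction and software are not given in the sources used here. In every array the mean of the signals, after leaving out the lowest and highest 2%, was 500.07 or 500.08, so the deposited intensity values had been scaled to a common trimmed mean. The table holds 57381 probe sets, of which 187 control probe sets were left out and 57194 were analysed. Values were turned into log2(signal + 20), where 20 is the median signal of 63.5 divided by 4 and rounded to 1 digit, and no further normalization was applied. The pseudocount shrinks log2 changes of dim genes. Within each organ a probe set was tested if its mean log2 value over the 12 arrays lay above the 40th percentile, which left 34316 in each organ, 30501 in both and 38131 in at least 1 organ. Precision is limited by the number of arrays, 3 per group. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

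Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. All adjusted p-values of genes below come from these limma fits. The 12 arrays of an organ shared 1 fit. Contrasts between organs, and differences of a response between organs, used all 24 arrays. Differences between times or organs were tested as interaction contrasts. The comparisons, tests, filter and most alternatives were chosen before the data were examined. The comparisons of 120 with 30 min within tZ, the difference between organs of each time effect, and tZ 120 min against DMSO 30 min were added after the results had been seen.

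Probe sets were named through the array's annotation and a RefSeq gene table of assembly ASM3414082v1, used for names only. A total of 22436 probe sets had exactly 1 gene, 95 several and 34663 none, and the 17905 genes represented were all found in the table. No product descriptions were in the tables, so the rule for naming genes, which asked for a described product, was applied to the 2451 genes with a name other than a locus or clone number. A gene with several probe sets was represented by the brightest. Genes named were those called with all 3 arrays of a group above or below all 3 of the other. For each tZ contrast they were the 12 with the largest rise and the 8 with the largest fall. For each time contrast they were the 6 largest in each direction, and for organ and difference contrasts the 5 largest. All tested type-A response regulators and cytokinin dehydrogenases were added, with the 2 members moving most in each direction of any other list that passed. Not every gene the rule selects is described, and other members of a list named here were picked after their values were seen.

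Shifts of 29 gene lists were tested with limma's camera at the preset inter-gene correlation of 0.01, over lists with at least 3 tested genes, with an estimated correlation and limma's fry as alternatives. fry asks whether a list moves on balance in 1 direction and compares it with no other genes. The lists were fixed in advance as text patterns, but these were written for product descriptions and only 10 lists matched any gene and 6 at least 3. They were therefore rewritten as patterns for gene symbols, after the name tables and array summaries had been seen and before any gene's values had been, which gave 27 lists of at least 3 genes. The lists cover type-A response regulators, cytokinin dehydrogenases, cytokinin synthesis and activation, cytokinin receptors with phosphotransfer proteins and type-B regulators, cytokinin response and GATA factors, and zeatin O-glucosyltransferases, which matched 0 genes. Hormone lists cover auxin-responsive genes, auxin transport, ethylene synthesis, and gibberellin, abscisic acid and jasmonate genes. The others are nitrate and ammonium, phosphate and sulfate, iron, expansins, cell cycle, histones and DNA replication, cytosolic ribosomal proteins, heat shock proteins, WRKY factors, class III peroxidases, glutaredoxins, aquaporins, hypoxia and fermentation, circadian clock and chlorophyll synthesis. Photosynthesis genes served as the leaf marker, and the Casparian strip list, with 1 gene, as the root marker.

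The fits were tested on simulated data. For root at 30 min, with 34316 probe sets, 14%, 50%, 80% and 96% of simulated changes of 1.5, 2, 4 and 8 fold were recovered. For leaf at 30 min, also with 34316, the shares were 44%, 64%, 94% and 100%. Unchanged probe sets made up 4% of the calls in root (5 probe sets) and 7.93% in leaf (13), the latter above the nominal 5%. Only 50 probe sets were changed at each simulated fold, whereas 33.7% and 45.6% of those tested were called in the data. The Benjamini-Hochberg adjustment was thus stricter in the simulation, and the shares recovered do not give the sensitivity of the reported comparisons. In the list test for these comparisons, a simulated list held 10 genes. Shifted by 0.5 or 1 on the log2 scale, it was called in 10 of 10 rounds. These rounds do not give the sensitivity or error rate of the reported list tests. There, genes of a list can be correlated and many other genes changed. In root at 30 min the estimated inter-gene correlation was 0.592 for hypoxia genes and 0.518 for type-A regulators. In leaf at 30 min it was -0.0604 and -0.0242. Alternatives to the pseudocount, filter, between-array scaling, variance model, arrays in the fit, array weights, threshold, probe set per gene and replicate block were tried, and each array was left out in turn. Tables were written with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15 and figures with matplotlib 3.10.9.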

Results

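Transcript levels were measured in 24 arrays covering 2 organs, 2 treatments and 2 incubation times, with 3 arrays per group. The median signal of an array ran from 68.2 to 86.7 in root and from 47.6 to 57.0 in leaf. Within a group, log2 values of replicate arrays correlated across probe sets at 0.960 to 0.982, and no pair was a duplicate. Levels below are means ± SD of 3 arrays in linear signal units, given as the first-named group against the second, and changes are on the log2(signal + 20) scale.

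The organ named in the titles was checked first, because the tissue field names root for every sample. In DMSO at 30 min the leaf arrays were high in photosynthesis genes. The ferredoxin-NADP reductase gene LFNR1 read 15652 ± 667 against 136 ± 8.87 in leaf and root. The rubisco activase gene OsrcaA1 read 25144 ± 1691 against 279 ± 27.3 and the rubisco small subunit gene OsrbcS 19738 ± 1266 against 349 ± 48.1. Adjusted p for these 3 genes ran from 5.3e-23 to 4.2e-19. OsCASP1, of the family that builds the Casparian strip in the root endodermis, read 2227 ± 152 in root and 15.9 ± 0.551 in leaf. The values followed the titles. CAB2R, a chlorophyll-binding protein gene, was high in both organs, at 24276 ± 832 against 9713 ± 738. The other 7 photosynthesis genes above 1000 in leaf lay at a median of 2.78% of their leaf level in root. Among the largest organ differences were the aquaporin gene OsPIP2;7 and OsGLK2, a transcription factor gene known for chloroplast development. They read 16962 ± 582 against 29.1 ± 21.8 and 7155 ± 11.8 against 9.33 ± 2.53. In all, 22926 of 38131 probe sets differed between the organs in limma, 9954 higher and 12972 lower in leaf. The share higher, 43.4%, became 50.5% after quantile normalization of all arrays and 62.5% with arrays shifted to the same median.

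The treatment labels were checked with the type-A response regulators, primary targets of cytokinin signalling known for rapid induction. Levels of OsRR6 and OsRR9 follow in the order DMSO 30 min, tZ 30 min, DMSO 120 min and tZ 120 min. OsRR6 read 2454 ± 167, 5086 ± 219, 17438 ± 317 and 15078 ± 2364 in root. In leaf it read 1144 ± 21.4, 2034 ± 94.1, 3899 ± 95.7 and 9758 ± 220.2. OsRR9 read 1956 ± 54.3, 1298 ± 96.3, 16091 ± 1237 and 10111 ± 1365 in root. In leaf it read 3104 ± 116, 989.8 ± 48.6, 12760 ± 782 and 12423 ± 523. In both organs all 5 tested members, OsRR1, OsRR2, OsRR4, OsRR6 and OsRR9, were higher in every array labelled DMSO 120 min than in any labelled tZ 30 min.

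Along the labelled time within DMSO the type-A list rose in both organs. In root it had 5 of 5 members higher and 0 lower (5 and 0 adjusted over the list alone). For this list the median log2 change was 2.22 (camera adjusted p = 3.1e-14, and adjusted p = 0.0436 with an estimated correlation). In leaf it had 3 of 5 members higher and 0 lower (3 and 0 adjusted over the list alone). For leaf the median log2 change was 1.26 (camera adjusted p = 4.4e-14, and adjusted p = 9.8e-04 with an estimated correlation). Against DMSO of the same labelled time the list passed camera in 1 of 4 comparisons. This test compares a list with the other genes, which changed more between treatments. Over all probe sets the median size of the log2 change was 0.31 to 0.38 in the 4 tZ comparisons. Along time in DMSO it was 0.19 in root and 0.13 in leaf. By fry the list passed as higher in root at 30 min (fry adjusted p = 7.2e-04) but not at 120 min (fry adjusted p = 0.0786). Root at 30 min had 3 of 5 members higher and 1 lower (4 and 1 adjusted over the list alone). For root at 30 min the median log2 change was 0.44 (camera adjusted p = 0.119, and adjusted p = 0.53 with an estimated correlation). Root at 120 min had 2 of 5 members higher and 1 lower (2 and 2 adjusted over the list alone). For root at 120 min the median log2 change was -0.085 (camera adjusted p = 0.578, and adjusted p = 0.748 with an estimated correlation). In root at 120 min the mean of the list, 0.33, differed in sign from the median, which was 0.028 with arrays shifted to the same median. Leaf at 30 min had 1 of 5 members higher and 2 lower (2 and 2 adjusted over the list alone). For leaf at 30 min the median log2 change was -0.30 (camera adjusted p = 0.797, and adjusted p = 0.805 with an estimated correlation). Leaf at 120 min had 4 of 5 members higher and 0 lower (4 and 0 adjusted over the list alone). For leaf at 120 min the median log2 change was 1.85 (camera adjusted p = 0.0113, and adjusted p = 0.0846 with an estimated correlation). By the pattern first written, which also took in 4 genes named as type-B, 4 of 9 members in leaf at 120 min were higher and 3 lower, and the list did not pass, with a median of 0.049 (camera adjusted p = 0.367). The 5 type-A genes went against the treatment labels in part. Groups are therefore called by their labels throughout, and each direction given for tZ rests on those labels. An exchange of the tZ 30 min and DMSO 120 min labels is taken up below. It would turn the comparisons of tZ with DMSO into comparisons of times. At labelled 30 min they would compare 120 with 30 min in DMSO, and at labelled 120 min the same times in tZ. The difference of the tZ effects between 120 and 30 min would keep its value.

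**Figure D1:**
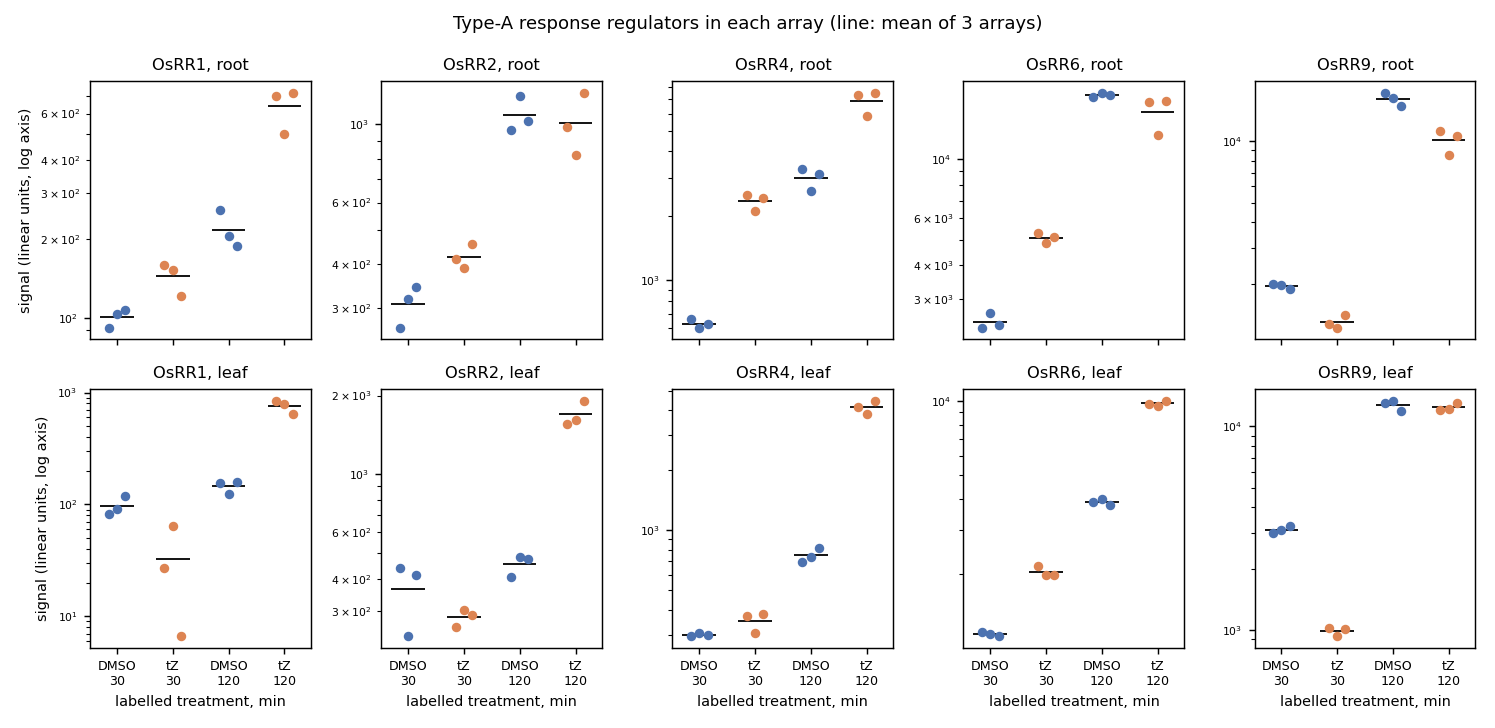
Signal of the type-A response regulator genes in each array (linear units on a log axis) by labelled treatment and time, points for arrays and lines for means of 3 arrays. All 5 genes are higher in each array labelled DMSO 120 min than in any labelled tZ 30 min, in root and in leaf.

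The comparison of tZ with DMSO in root at 30 min asked which transcripts respond early to the cytokinin. Genes of hypoxia and fermentation were higher in arrays labelled tZ. The pyruvate decarboxylase gene PDC1 read 22479 ± 904 against 178 ± 4.25, a log2 change of 6.82 (SE 0.12, adjusted p = 2.6e-15). The non-symbiotic hemoglobin gene NSHB2 read 42419 ± 3374 against 2886 ± 356, a change of 3.87 (SE 0.10, adjusted p = 1.1e-13). Hypoxia genes had 5 of 6 members higher and 0 lower (5 and 0 adjusted over the list alone). For hypoxia genes the median log2 change was 2.00 (camera adjusted p = 8.3e-06, and adjusted p = 0.385 with an estimated correlation). Also higher were the kinase gene CPDK2 at 22507 ± 1126 against 705 ± 62.4 and OsCCR1 at 2096 ± 92.3 against 64.8 ± 21.7. The zinc finger gene OsC3H37 read 29340 ± 914 against 2180.1 ± 77.3 and the expansin-like gene OsEXLA2 6864 ± 314 against 677 ± 71.5. SMR1, a cyclin-dependent kinase inhibitor gene, read 18811 ± 376 against 2201 ± 241. Adjusted p for these 5 genes ran from 1.9e-14 to 7.6e-11.

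The lowest genes in root arrays labelled tZ at 30 min included DREB1 transcription factor genes, which are known from cold responses. DREB1G read 41.9 ± 19.7 against 4424 ± 135, a change of -6.22 (SE 0.76, adjusted p = 7.4e-06). Its level in tZ lay below the median signal of the arrays, so the size of the change depends on the pseudocount, at -6.66 with a smaller and -5.22 with a larger one. OsDREB1B.1 read 236 ± 31.7 against 5188 ± 84.9 and the calmodulin-like gene CML10 210.2 ± 10.3 against 8002 ± 430.4. The jasmonate repressor gene OsTIFY11a read 351 ± 38.0 against 7742 ± 363, the trehalose phosphatase gene OsTPP7 990.3 ± 70.9 against 12857 ± 124 and BHLH148 870.2 ± 129 against 9170.1 ± 108. Adjusted p for the last 5 genes ran from 4.8e-07 to 8.4e-06. Photosynthesis genes had 0 of 9 members higher and 7 lower (0 and 7 adjusted over the list alone). For photosynthesis genes the median log2 change was -1.11 (camera adjusted p = 0.0154, and adjusted p = 0.385 with an estimated correlation). CAB2R read 1226 ± 20.2 against 9713 ± 738. Abscisic acid genes had 3 of 3 members higher and 0 lower (3 and 0 adjusted over the list alone). For abscisic acid genes the median log2 change was 0.77 (camera adjusted p = 0.0443, and adjusted p = 0.385 with an estimated correlation). The zeaxanthin epoxidase gene OsABA1 read 1079 ± 176 against 382 ± 31.1 and the catabolic gene OsABA8ox2 253 ± 35.1 against 139 ± 14.8.

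Cytokinin genes in root at 30 min moved in both directions. Of the type-A regulators OsRR4 was higher by 1.86 (SE 0.11, adjusted p = 1.9e-09) and OsRR6 by 1.05 (SE 0.093, adjusted p = 2.8e-07). OsRR9 changed by -0.59 (SE 0.092, adjusted p = 1.0e-04), and OsRR1 did not pass at 0.44 (SE 0.19). OsRR2, at 0.42 (SE 0.15, adjusted p = 0.0337), did not pass without replicate 1 or 2 of DMSO (0.32 and 0.45) or replicate 1 or 3 of tZ (0.43 and 0.37). Among the cytokinin dehydrogenases, which degrade cytokinins, OsCKX11 was higher at 6918 ± 174 against 1416 ± 93.1 and OsCKX3 lower at 33.2 ± 19.6 against 109 ± 23.3. The OsCKX3 level in tZ lay below the median signal of the arrays, so the size of its change depends on the pseudocount. OsCKX4, at -0.65 (SE 0.19, adjusted p = 0.0126), did not pass without replicate 2 of tZ, at -0.46. Cytokinin dehydrogenases had 1 of 5 members higher and 2 lower (1 and 2 adjusted over the list alone). For cytokinin dehydrogenases the median log2 change was -0.62 (camera adjusted p = 0.975, and adjusted p = 0.983 with an estimated correlation). For that list fry gave the opposite direction to the median. In total 11571 of the 34316 probe sets tested changed at an adjusted p below 0.05 in limma, 4758 higher and 6813 lower. These directions rest on treatment labels that the type-A regulators did not follow throughout.

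At 120 min in root the question was which transcripts differ after longer exposure. PDC1 was far higher in arrays labelled tZ, at 16149 ± 2910.2 against 95.4 ± 15.1 and a change of 7.12 (SE 0.12, adjusted p = 1.7e-15). NSHB2 read 35056 ± 4567 against 3114 ± 176, CPDK2 12304 ± 2177 against 642 ± 107 and OsC3H37 28979 ± 3708 against 1663 ± 102. Hypoxia genes had 5 of 6 members higher and 0 lower (5 and 0 adjusted over the list alone). For hypoxia genes the median log2 change was 1.88 (camera adjusted p = 7.1e-07, and adjusted p = 0.25 with an estimated correlation). Abscisic acid genes had 3 of 3 members higher and 0 lower (3 and 0 adjusted over the list alone). For abscisic acid genes the median log2 change was 1.41 (camera adjusted p = 0.00278, and adjusted p = 0.25 with an estimated correlation). OsABA8ox2 read 477 ± 143 against 162 ± 8.65. Lower were DREB1G at 572 ± 881 against 2515 ± 174, CML10 at 1179 ± 1649 against 6321 ± 480.3 and OsTIFY11a at 1310 ± 1316 against 5892 ± 570.3. The metal transporter gene OsHMA2 read 155 ± 129.7 against 1079 ± 458 and the homeobox gene OsHox2 328 ± 55.1 against 1647 ± 229. Across these 5 genes adjusted p ran from 1.3e-05 to 0.00203. In replicate 2 of the tZ group DREB1G read 1589.9, against 51.1 and 76.5 in the other arrays. Without it the change of DREB1G went from -3.51 to -4.93. For CML10 it went from -3.47 to -4.68 and for OsTIFY11a from -2.60 to -3.38.

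Of the type-A regulators in root at 120 min, OsRR1 was higher by 1.47 (SE 0.19, adjusted p = 2.1e-05) and OsRR4 by 1.18 (SE 0.11, adjusted p = 5.5e-07). OsRR9 changed by -0.68 (SE 0.092, adjusted p = 3.8e-05), and OsRR2 and OsRR6 did not pass at -0.085 (SE 0.15) and -0.22 (SE 0.093). OsRR2 was at 0.0059 and 0.052 without replicate 2 of DMSO or of tZ. Without replicate 1 or 3 of tZ, OsRR6 passed at -0.29, and after quantile normalization of all arrays at -0.37. Of the cytokinin dehydrogenases, OsCKX11 at 7574 ± 944 against 2267 ± 118 and OsCKX5 at 2966 ± 663 against 1218 ± 62.7 were higher. OsCKX4 at 395 ± 62.6 against 916 ± 135 was lower, and OsCKX3, at -0.77 (SE 0.28, adjusted p = 0.0493), did not pass with any of the 6 arrays left out (-0.89 to -0.65). Nor did OsCKX3 pass with a smaller pseudocount (-0.82) or after quantile normalization of all arrays (-0.70). The dehydrogenase list had 2 of 5 members higher and 2 lower (2 and 2 adjusted over the list alone). For the dehydrogenase list the median log2 change was 0.85 (camera adjusted p = 0.311, and adjusted p = 0.743 with an estimated correlation). In all 10395 of the 34316 probe sets tested changed at an adjusted p below 0.05 in limma, 3919 higher and 6476 lower. The share higher, 37.7%, became 54.0% with arrays shifted to the same median. Across the 34316 probe sets the changes at 30 and 120 min correlated at a Pearson r of 0.756, where probe sets are not independent replicates. Of the calls, 2916 were higher and 4394 lower at both times, where independence of the calls at both times gives 543 and 1286, and 145 had opposite signs. Calls at both times shared 1 estimate of the spread per probe set, which can itself add to this overlap. These directions too follow labels that the type-A regulators contradict in part.

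Whether the root response differed between the times was tested as the difference of the tZ effects, 120 min minus 30 min. The pathogenesis-related gene PBZ1 differed by -2.44 (SE 0.12, adjusted p = 3.8e-08). Its levels were 1744 ± 20.8, 5167 ± 205, 7688 ± 484 and 4161 ± 498 in DMSO 30 min, tZ 30 min, DMSO 120 min and tZ 120 min. The auxin efflux carrier gene OsPIN4 differed by -1.72 (SE 0.36, adjusted p = 0.0122) and OsRR6 by -1.27 (SE 0.13, adjusted p = 1.0e-04). OsCKX5 differed by 1.47 (SE 0.20, adjusted p = 6.3e-04) and the seed storage gene PROLM25 by 3.89 (SE 0.80, adjusted p = 0.0113). PROLM25 read 290 ± 17.1 in DMSO at 30 min and at most 45.2 ± 64.0 in the other root groups, below the median signal, and its difference was 2.31 with a larger pseudocount. In all 1578 of the 34316 probe sets tested differed at an adjusted p below 0.05 in limma, 892 higher and 686 lower. The count was 848 without replicate 2 of DMSO 30 min. It was 957 to 1042 without replicate 1 of DMSO 30 min, 2 or 3 of tZ 30 min, or 2 or 3 of DMSO 120 min. The share higher, 56.5%, became 83.4% with arrays shifted to the same median.

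In leaf at 30 min, arrays labelled tZ had far higher levels of the alcohol dehydrogenase gene Adh2, at 13147 ± 97.5 against 84.8 ± 10.1, a change of 6.98 (SE 0.076, adjusted p = 4.4e-18). Hypoxia genes had 5 of 6 members higher and 0 lower (5 and 0 adjusted over the list alone). For hypoxia genes the median log2 change was 2.11 (camera adjusted p = 0.00474, and adjusted p = 0.0875 with an estimated correlation). Also higher were OsC3H37 at 8367 ± 489.8 against 743 ± 16.9 and the carotenoid cleavage dioxygenase gene OsCCD8a at 419.6 ± 35.5 against 26.1 ± 18.7. The beta-tubulin gene TUB2 read 2279 ± 111 against 317 ± 35.4, the auxin-related gene SAUR39 3266 ± 443 against 408 ± 58.1 and OsCKX11 2018 ± 79.0 against 339.7 ± 42.8. Adjusted p for these 5 genes ran from 1.9e-16 to 1.3e-07. Cytosolic ribosomal protein genes were higher as a list. Ribosomal protein genes had 22 of 25 members higher and 3 lower (22 and 3 adjusted over the list alone). For ribosomal protein genes the median log2 change was 0.89 (camera adjusted p = 2.8e-09, and adjusted p = 0.0117 with an estimated correlation). RPS26 read 10307 ± 1079 against 3041 ± 112, and a lower member was CL27 at 2460.1 ± 29.2 against 2991 ± 195. This list was matched by gene symbol without product descriptions, so a member such as CL27 need not encode a cytosolic protein. Histone and replication genes had 12 of 23 members higher and 0 lower (13 and 1 adjusted over the list alone). For histone and replication genes the median log2 change was 0.34 (camera adjusted p = 0.0276, and adjusted p = 0.0875 with an estimated correlation). Lower were DREB1G at 42.4 ± 10.2 against 3357 ± 266 and the WRKY transcription factor gene OsWRKY76 at 239 ± 12.8 against 11137 ± 253. The jasmonate repressor gene OsTIFY11e read 1230.1 ± 157 against 13859 ± 867 and the potassium channel gene OsKCO2 94.8 ± 11.2 against 1359.7 ± 39.4. Adjusted p for these 4 genes ran from 4.7e-15 to 1.9e-11.

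Many lists were lower in leaf arrays labelled tZ at 30 min. Photosynthesis genes had 0 of 9 members higher and 9 lower (0 and 9 adjusted over the list alone). For photosynthesis genes the median log2 change was -0.80 (camera adjusted p = 5.0e-05, and adjusted p = 0.0875 with an estimated correlation). RCABP69 read 934 ± 263 against 5720.5 ± 504. Chlorophyll synthesis genes had 0 of 8 members higher and 6 lower (0 and 7 adjusted over the list alone). For chlorophyll synthesis genes the median log2 change was -0.93 (camera adjusted p = 0.00474, and adjusted p = 0.0875 with an estimated correlation). CHLH, a magnesium chelatase subunit gene, read 1301 ± 232 against 4276 ± 139. Cytokinin synthesis genes had 1 of 8 members higher and 6 lower (1 and 6 adjusted over the list alone). For cytokinin synthesis genes the median log2 change was -1.03 (camera adjusted p = 0.0106, and adjusted p = 0.0875 with an estimated correlation). The cytokinin-activating enzyme gene LOG read 1836 ± 129 against 7541 ± 220.2 and its relative LOGL3 546 ± 32.2 against 5254 ± 359. Jasmonate genes had 6 of 34 members higher and 18 lower (6 and 19 adjusted over the list alone). For jasmonate genes the median log2 change was -0.51 (camera adjusted p = 0.00269, and adjusted p = 0.0875 with an estimated correlation). WRKY genes had 1 of 6 members higher and 4 lower (1 and 4 adjusted over the list alone). For WRKY genes the median log2 change was -0.84 (camera adjusted p = 0.0276, and adjusted p = 0.124 with an estimated correlation). Glutaredoxins had 3 of 16 members higher and 9 lower (3 and 9 adjusted over the list alone). For glutaredoxins the median log2 change was -0.39 (camera adjusted p = 0.0276, and adjusted p = 0.0875 with an estimated correlation). Aquaporins had 7 of 22 members higher and 12 lower (7 and 12 adjusted over the list alone). For aquaporins the median log2 change was -0.44 (camera adjusted p = 0.0406, and adjusted p = 0.0875 with an estimated correlation). Abscisic acid genes had 0 of 3 members higher and 3 lower (0 and 3 adjusted over the list alone). For abscisic acid genes the median log2 change was -0.91 (camera adjusted p = 0.019, and adjusted p = 0.166 with an estimated correlation). The glutaredoxin gene GRXS5 read 2584 ± 96.5 against 14026 ± 443, the water channel gene OsTIP2;2 337 ± 38.0 against 2893 ± 173 and OsABA8ox1 10978 ± 788 against 20595 ± 1022.

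Of the type-A regulators in leaf at 30 min, OsRR6 was higher by 0.82 (SE 0.05, adjusted p = 7.9e-10). OsRR9 changed by -1.63 (SE 0.058, adjusted p = 8.9e-13) and OsRR1 by -1.30 (SE 0.29, adjusted p = 0.00157), against the treatment label on which every direction in this comparison rests. OsRR2 and OsRR4 did not pass at -0.30 (SE 0.16) and 0.21 (SE 0.092). OsRR2 passed at -0.55 without replicate 2 of DMSO, and OsRR4 at 0.31 without replicate 2 of tZ. OsCKX5 read 152 ± 33.8 against 297 ± 31.2. OsCKX4 read 526 ± 46.8 against 632 ± 35.8, a change of -0.26 (SE 0.084, adjusted p = 0.0189) that did not pass without replicate 2 of DMSO (-0.22) or of tZ (-0.18). In all 15637 of the 34316 probe sets tested changed at an adjusted p below 0.05 in limma, 8140 higher and 7497 lower. The share higher, 52.1%, became 48.6% with arrays shifted to the same median.

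**Figure D2:**
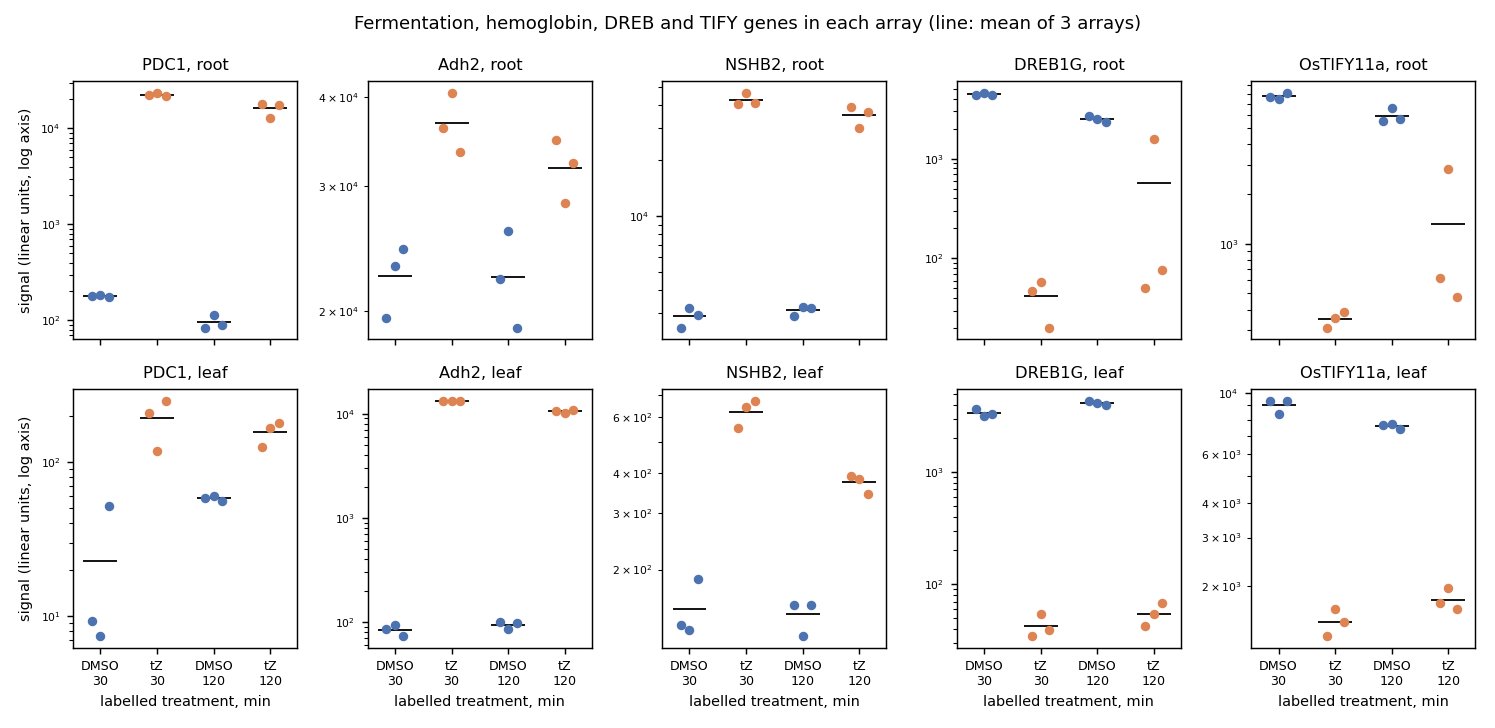
Signal of fermentation, hemoglobin, DREB and TIFY genes in each array (linear units on a log axis) by labelled treatment and time, points for arrays and lines for means of 3 arrays. PDC1, Adh2 and NSHB2 lie higher and DREB1G and OsTIFY11a lower in arrays labelled tZ than in DMSO of the same organ and time, and replicate 2 of root tZ 120 min stands apart for DREB1G.

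At 120 min in leaf, Adh2 read 10493 ± 334 against 94.6 ± 7.50, a change of 6.52 (SE 0.076, adjusted p = 6.3e-18), and the pyruvate decarboxylase gene PDC2 15723 ± 613 against 3338 ± 46.5. Hypoxia genes had 5 of 6 members higher and 0 lower (5 and 0 adjusted over the list alone). For hypoxia genes the median log2 change was 1.31 (camera adjusted p = 0.00717, and adjusted p = 0.0846 with an estimated correlation). Here 4 of the 5 type-A regulators were higher with labelled tZ. OsRR4 read 4139.9 ± 307 against 749 ± 62.3, OsRR1 758 ± 102 against 147 ± 19.1 and OsRR2 1696 ± 187 against 455 ± 43.3. OsRR6 read 9758 ± 220.2 against 3899 ± 95.7, while OsRR9 did not pass at -0.038 (SE 0.058). Cytokinin dehydrogenases had 3 of 3 members higher and 0 lower (3 and 0 adjusted over the list alone). For cytokinin dehydrogenases the median log2 change was 1.35 (camera adjusted p = 0.0146, and adjusted p = 0.0846 with an estimated correlation). OsCKX11 read 2301 ± 41.6 against 358 ± 32.4 and OsCKX4 2941 ± 174 against 1146 ± 96.0. OsCCD8a read 733 ± 13.1 against 19.5 ± 17.5, TUB2 3045 ± 194 against 374 ± 21.6 and the alpha-amylase gene AMY1.3 509.9 ± 79.8 against 88.5 ± 10.8. Ribosomal protein genes had 22 of 25 members higher and 3 lower (22 and 3 adjusted over the list alone). For ribosomal protein genes the median log2 change was 0.87 (camera adjusted p = 1.3e-09, and adjusted p = 0.0104 with an estimated correlation). Lower were OsWRKY76 at 97.7 ± 30.2 against 9408 ± 282, DREB1G at 54.6 ± 12.8 against 4135 ± 189.6 and OsDREB1B.1 at 1046 ± 59.8 against 9275 ± 285. Their adjusted p ran from 2.5e-15 to 8.1e-15.

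Among lists lower in leaf at 120 min were photosynthesis and phosphate genes. Photosynthesis genes had 0 of 9 members higher and 9 lower (0 and 9 adjusted over the list alone). For photosynthesis genes the median log2 change was -0.68 (camera adjusted p = 4.5e-04, and adjusted p = 0.0966 with an estimated correlation). Phosphate and sulfate genes had 0 of 12 members higher and 7 lower (0 and 8 adjusted over the list alone). For phosphate and sulfate genes the median log2 change was -0.44 (camera adjusted p = 0.0347, and adjusted p = 0.121 with an estimated correlation). OsPht1;4 read 447 ± 38.3 against 816 ± 102. The lists of chlorophyll synthesis, cytokinin synthesis, aquaporins, jasmonate, WRKY and abscisic acid genes passed as well, with medians of -0.72, -1.20, -0.57, -0.26, -0.53 and -1.21. In that order, 6 of 8, 6 of 8, 13 of 22, 18 of 34, 4 of 6 and 3 of 3 members were lower, and 6, 6, 13, 18, 4 and 3 adjusted over the list alone. Members higher numbered 0, 1, 5, 5, 0 and 0, and 0, 1, 5, 5, 0 and 0 adjusted over the list alone. Camera adjusted p for the 6 lists ran from 0.0112 to 0.0222, and adjusted p from 0.0846 to 0.14 with an estimated correlation. The jasmonate synthesis gene OsOPR4 read 869 ± 26.8 against 5411 ± 51.2, LOGL3 434 ± 51.5 against 4838 ± 671 and the water channel gene OsPIP2;6 314 ± 45.9 against 1583 ± 61.2. In all 14906 of the 34316 probe sets tested changed at an adjusted p below 0.05 in limma, 7549 higher and 7357 lower. The share higher, 50.6%, became 44.3% with arrays shifted to the same median. The changes at 30 and 120 min correlated across probe sets at a Pearson r of 0.842. Of the calls, 6271 were higher and 6068 lower at both times, where independence gives 1791 and 1607. As in root, calls at both times shared 1 estimate of the spread per probe set. Of the 5 type-A regulators, 4 were higher with labelled tZ at 120 min and 1 at 30 min.

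The difference between the leaf responses at 120 and 30 min included cytokinin genes. OsRR1 differed by 3.52 (SE 0.42, adjusted p = 7.6e-05), OsRR4 by 2.22 (SE 0.13, adjusted p = 3.5e-08) and OsRR2 by 2.15 (SE 0.23, adjusted p = 2.8e-05). OsRR9 differed by 1.59 (SE 0.082, adjusted p = 8.5e-09) and OsCKX5 by 1.84 (SE 0.24, adjusted p = 1.6e-04). In the opposite direction the late embryogenesis gene LEA19 differed by -2.86 (SE 0.31, adjusted p = 2.9e-05). OsCHS1, the chalcone synthase gene at the entry of flavonoid synthesis, differed by -2.04 (SE 0.12, adjusted p = 2.6e-08). It read 2952 ± 290.5, 3503 ± 281, 3120.4 ± 101 and 891 ± 84.0 in DMSO 30 min, tZ 30 min, DMSO 120 min and tZ 120 min. In all 1316 of the 34316 probe sets tested differed at an adjusted p below 0.05 in limma, 698 higher and 618 lower.

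Whether the response differed between organs was tested as the leaf effect minus the root effect. Under an exchange of the tZ 30 min and DMSO 120 min labels, it would instead compare an effect of time between the organs. At 30 min Adh2 differed by 6.26 (SE 0.14, adjusted p = 3.9e-19), and its root level in DMSO was 22403 ± 2566. PDC1 differed by -4.41 (SE 0.36, adjusted p = 7.4e-10), OsWRKY76 by -3.69 (SE 0.22, adjusted p = 2.6e-12) and the homeobox gene OsHox4 by 3.73 (SE 0.16, adjusted p = 8.3e-15). At 120 min Adh2 differed by 6.01 (SE 0.14, adjusted p = 1.0e-18) and PDC1 by -5.95 (SE 0.36, adjusted p = 3.9e-12). OsHox2, lower with labelled tZ in root and higher in leaf, differed by 4.97 (SE 0.37, adjusted p = 1.0e-10), and TUB2 by 3.77 (SE 0.11, adjusted p = 1.9e-17). OsRR4 differed by -1.64 (SE 0.15, adjusted p = 3.2e-09) at 30 min and by 1.25 (SE 0.15, adjusted p = 2.4e-07) at 120 min. At 30 min 11270 of the 30501 probe sets tested differed at an adjusted p below 0.05 in limma, 6579 higher and 4691 lower. At 120 min 11126 of the 30501 probe sets tested differed at an adjusted p below 0.05 in limma, 6282 higher and 4844 lower. The share higher at 120 min, 56.5%, became 40.7% with arrays shifted to the same median. Across 30501 probe sets the root and leaf changes correlated at a Pearson r of 0.354 at 30 min and 0.239 at 120 min.

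The change over labelled time in arrays labelled DMSO was examined as the background of the excised organ. It rests on the label DMSO 120 min. If the labels of tZ 30 min and DMSO 120 min were exchanged, a possibility taken up below, it would instead compare tZ with DMSO at 30 min. In root this change included cytokinin genes. OsRR9 read 16091 ± 1237 against 1956 ± 54.3 at 120 against 30 min, OsRR6 17438 ± 317 against 2454 ± 167 and OsRR4 3019 ± 361 against 629 ± 30.3. OsCKX4 read 916 ± 135 against 163 ± 14.2 and PBZ1 7688 ± 484 against 1744 ± 20.8. Adjusted p for these 5 genes ran from 5.4e-11 to 3.3e-06. Cytokinin dehydrogenases had 4 of 5 members higher and 0 lower (4 and 0 adjusted over the list alone). For cytokinin dehydrogenases the median log2 change was 1.17 (camera adjusted p = 1.3e-06, and adjusted p = 0.0648 with an estimated correlation). Ribosomal protein genes had 10 of 25 members higher and 0 lower (17 and 0 adjusted over the list alone). For ribosomal protein genes the median log2 change was 0.22 (camera adjusted p = 1.9e-08, and adjusted p = 0.0648 with an estimated correlation). Histone and replication genes had 2 of 30 members higher and 0 lower (8 and 0 adjusted over the list alone). For histone and replication genes the median log2 change was 0.17 (camera adjusted p = 0.0102, and adjusted p = 0.0648 with an estimated correlation). WRKY genes had 0 of 6 members higher and 3 lower (0 and 4 adjusted over the list alone). For WRKY genes the median log2 change was -0.44 (camera adjusted p = 0.00205, and adjusted p = 0.106 with an estimated correlation). Photosynthesis genes had 0 of 9 members higher and 1 lower (0 and 7 adjusted over the list alone). For photosynthesis genes the median log2 change was -0.64 (camera adjusted p = 9.3e-04, and adjusted p = 0.106 with an estimated correlation). LOGL3 read 338 ± 46.5 against 1092 ± 57.3, the plastocyanin gene PETE 1618 ± 286 against 3131 ± 253 and PROLM25 8.23 ± 2.63 against 290 ± 17.1. In all 2137 of the 34316 probe sets tested changed at an adjusted p below 0.05 in limma, 1113 higher and 1024 lower. The share higher, 52.1%, became 28.0% with arrays shifted to the same median. The count was 1203 without replicate 2 of DMSO 30 min, and 1294 to 1362 without replicate 1 or 3 of DMSO 30 min or 2 or 3 of DMSO 120 min. It was higher without replicate 2 of tZ 120 min, which shares the fit, as given below.

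In leaf the time effect in arrays labelled DMSO, under the same limit of the labels, again included cytokinin genes. OsRR9 read 12760 ± 782 against 3104 ± 116, OsRR6 3899 ± 95.7 against 1144 ± 21.4 and OsRR4 749 ± 62.3 against 301 ± 4.51. OsCKX4 read 1146 ± 96.0 against 632 ± 35.8, and adjusted p for these 4 genes ran from 6.6e-12 to 1.1e-04. Lower were the linalool synthase gene OsLIS at 259.8 ± 61.7 against 579.6 ± 91.3 and the vitamin B6 synthesis gene PDX12 at 1209.9 ± 94.99 against 1941 ± 90.2. Jasmonate genes had 0 of 34 members higher and 4 lower (0 and 9 adjusted over the list alone). For jasmonate genes the median log2 change was -0.086 (camera adjusted p = 1.5e-04, and adjusted p = 0.0738 with an estimated correlation). Ribosomal protein genes had 1 of 25 members higher and 0 lower (6 and 0 adjusted over the list alone). For ribosomal protein genes the median log2 change was 0.083 (camera adjusted p = 7.7e-04, and adjusted p = 0.0738 with an estimated correlation). Photosynthesis genes had 0 of 9 members higher and 0 lower (0 and 1 adjusted over the list alone). For photosynthesis genes the median log2 change was -0.085 (camera adjusted p = 0.0165, and adjusted p = 0.335 with an estimated correlation). In all 481 of the 34316 probe sets tested changed at an adjusted p below 0.05 in limma, 243 higher and 238 lower. The count was 146 without replicate 2 of DMSO 120 min, and 180 to 285 without replicate 1 or 3 of either group. The share higher, 50.5%, became 71.6% with arrays shifted to the same median.

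Other lists passed camera in no comparison of tZ with DMSO or of the times. Part of their members changed between tZ and DMSO at 30 min, and counts in parentheses are those adjusted over the list alone. Cytokinin receptors, phosphotransfer proteins and type-B regulators had 1 higher and 3 lower of 10 (3 and 3) in root. In leaf they had 2 higher and 6 lower of 10 (2 and 6), and OsHpt5 changed by -2.05 (adjusted p = 2.4e-10). Cytokinin response and GATA factors had 1 higher and 0 lower of 4 (1 and 0) in root and 0 higher and 1 lower of 3 (0 and 1) in leaf. Auxin-responsive genes had 7 higher and 12 lower of 49 (7 and 12) in root and 12 higher and 19 lower of 45 (12 and 19) in leaf. Auxin transport had 2 higher and 1 lower of 4 (2 and 1) in root and 2 higher and 1 lower of 4 (2 and 1) in leaf. Gibberellin metabolism had 2 higher and 1 lower of 8 (2 and 1) in root and 3 higher and 3 lower of 7 (3 and 3) in leaf. Nitrate and ammonium genes had 1 higher and 6 lower of 17 (1 and 6) in root and 1 higher and 2 lower of 15 (1 and 2) in leaf. Iron genes had 2 higher and 9 lower of 18 (2 and 9) in root and 9 higher and 4 lower of 18 (9 and 5) in leaf. Expansins had 3 higher and 14 lower of 24 (3 and 14) in root and 2 higher and 5 lower of 17 (2 and 5) in leaf. Cell cycle genes had 7 higher and 8 lower of 30 (7 and 8) in root and 5 higher and 5 lower of 26 (5 and 5) in leaf. Heat shock proteins had 15 higher and 10 lower of 42 (16 and 10) in root and 11 higher and 14 lower of 43 (11 and 16) in leaf. Clock genes had 1 higher and 0 lower of 6 (2 and 2) in root and 0 higher and 3 lower of 6 (0 and 3) in leaf. With at least 3 tested members in root only, ethylene synthesis had 0 higher and 2 lower of 3 (0 and 2) and class III peroxidases 0 higher and 1 lower of 3 (0 and 1). Camera adjusted p for these lists at 30 min lay between 0.0947 and 0.987. The root marker OsCASP1 did not pass at 0.15 (SE 0.075).

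**Figure D3:**
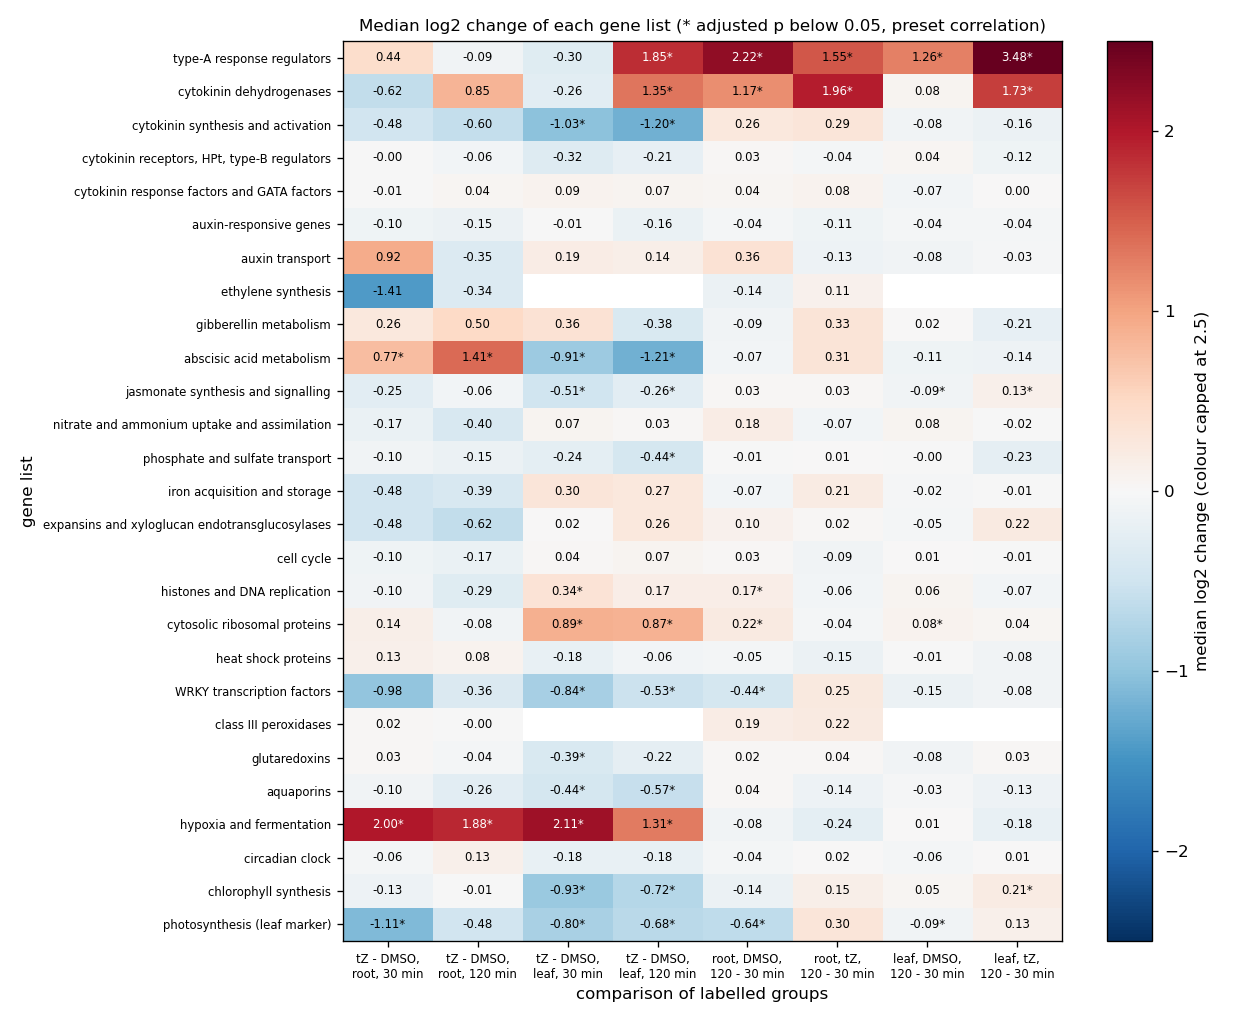
Median log2 change of each gene list (vertical axis) in each comparison of labelled groups (horizontal axis), with an asterisk where the camera adjusted p lay below 0.05 at the preset correlation. Hypoxia genes are higher with labelled tZ in all 4 comparisons, with medians of 1.31 to 2.11 (adjusted p = 0.0846 to 0.385 with an estimated correlation), and type-A response regulators are higher at the later labelled time, with medians of 1.26 to 3.48 (adjusted p = 3.9e-04 to 0.0538 with an estimated correlation). The medians of the lists marked kept their sign under each scaling tried.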

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

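The tests of exchanged labels, of a mixture, of a weaker response and of leaf tissue in root samples, and the comparisons of time effects between organs, were chosen after the results had been seen, while the test of RNA quality and the counts of other splits were chosen before.

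Each difference between groups below was tested as an interaction contrast, beside 100 random splits of the same arrays. In root, 1578 probe sets responded differently to labelled tZ at 120 and 30 min, and 1 split of 100 (the labelled one) gave as many. The highest of the others was 1527, and the highest without a labelled contrast was 1. Splits that mix labelled groups add the labelled effect to the spread within groups, and splits that keep 1 labelled contrast carry its effect. The splits therefore cannot tell a difference of responses from chance, here or in the other differences below. The root count of 1578 was 848 to 1042 without root DMSO 30 min replicate 1 or 2, tZ 30 min replicate 2 or 3, or DMSO 120 min replicate 2 or 3. In leaf, 1316 responded differently between the times, and 5 of the 100 splits, the labelled one included, gave as many, with 18311 the highest of the others, so the 100 splits as a whole do not exclude chance. The other 4 kept the labelled grouping in 1 of the contrasts subtracted and so carried its response, and no split without it exceeded 2. The response differed between leaf and root for 11270 probe sets at 30 min, where 2 of 100 splits gave as many (highest other 14492). At 120 min it differed for 11126, where 1 did (highest other 9065). The highest without a labelled contrast was 2 and 1, and for the reason given the splits decide neither. The time effect differed between the organs for 844 probe sets in DMSO, where 7 of 100 splits gave as many (highest other 1987), so these as a whole do not exclude chance either. Again the other 6 carried a labelled contrast, and no split without one exceeded 3. The count of 844 was 553 without root DMSO 30 min replicate 2, and 502 to 527 without leaf DMSO 30 min replicate 3 or leaf DMSO 120 min replicate 2 or 3. Its share higher, 52.8%, became 80.7% with arrays shifted to the same median. In tZ the time effect differed between the organs for 1231 probe sets, where 2 of 100 splits gave as many (highest other 3439). No split without a labelled contrast exceeded 5, and the splits do not decide this difference either.

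For comparisons of 3 arrays with 3, 10 splits exist, too few for a share under 0.05. In each of them 1 of the 10 splits, the labelled one, gave as many calls. Every other split mixes the labelled groups and so adds the labelled effect to the spread within groups. Few calls are then bound to result, and these splits cannot tell the labelled effect from chance. The labelled split gave 11571 calls in root at 30 min (highest other 0), 10395 in root at 120 min (1), 15637 in leaf at 30 min (0) and 14906 in leaf at 120 min (0). For the times it gave 2137 in root DMSO (highest other 0), 2312 in root tZ (1), 481 in leaf DMSO (2) and 2749 in leaf tZ (1), and for the organs 22926 (1).

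Type-A response regulators differed along the labelled time and hypoxia genes along the labelled treatment at camera's preset correlation, while with an estimated correlation the hypoxia list passed in 0 of 4 tZ comparisons (adjusted p = 0.0846 to 0.385) and the type-A list in 3 of 4 time comparisons (adjusted p = 0.0538 in root tZ). An exchange of DMSO and tZ throughout forbids a higher type-A median with labelled tZ, yet the largest of the 4 medians was 1.85, although it was 0.16 and decides nothing for the list by its first pattern, which also held 4 genes named as type-B. RNA quality is argued against as the source, since the mean log2 ratio of 3' to 5' control signal differed by only 0.086 in root and -0.013 in leaf between labelled treatments, although single controls moved in both directions, from -0.21 for gapdh to 0.27 for ubiquitin in root, where the ubiquitin ratios did not overlap, and from -0.26 for actin to 0.21 for cyclophilin in leaf. An exchange of the labels of the tZ 30 min and DMSO 120 min groups needs type-A levels to be lower in the former. The median log2 difference was -1.30 in root and -1.05 in leaf, with all 5 members lower in every array. By the first pattern it was -0.55 and -0.75, short of the size the test asked for, so the list by that pattern decides nothing. Such an exchange in both organs may therefore account for the pattern, as a hypothesis found in and tested on the same arrays, although OsCKX11, unlike the other dehydrogenases tested, was higher in labelled tZ 30 min than in DMSO 120 min (6918 and 2267 in root, 2018 and 358 in leaf), while a biological difference, with type-A genes rising during incubation in DMSO and hypoxia genes responding to tZ, stays open and was not tested.

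Replicate 2 of root tZ 120 min lay between its group and root DMSO 30 min. A uniformly weaker response forbids unequal positions on the log2 scale, but its median position was 0.622 for the 78 probe sets higher in DMSO 30 min and 0.114 for the 176 lower there, a difference of 0.509. On the linear scale the positions were 0.344 and 0.294, a difference of 0.0498, as a mixture with RNA of the DMSO 30 min type would give, so a mixed sample may account for this array. A fit of the array by group means gave a weight of 0.410 to its own group and 0.272 to DMSO 30 min. It gave 0.187 to tZ 30 min and 0.0927 to DMSO 120 min. Replicates 1 and 3 had 9.6e-79 and 2.8e-61 for DMSO 30 min. They had 0.650 and 0.618 for their own group and 0.344 and 0.373 for tZ 30 min. The own-group mean left out only the array fitted, so for replicates 1 and 3 it included replicate 2. Their weights are thus no clean yardstick, and the parts of replicate 2 are not resolved. No biological explanation was tested.

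CAB2R was bright in root DMSO arrays, at 40.01% of its leaf level. Leaf tissue would bring all abundant leaf transcripts, but the other 7 photosynthesis genes lay at a median of 2.78% of their leaf level, which argues against leaf tissue as the source of the CAB2R signal. Other sources, and a biological one, were not tested.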

How the results depend on the processing

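Alternatives for the comparisons added later, the fit without root tZ 120 min replicate 2 where its group is not compared, and the lists by their first patterns were chosen after the results had been seen. Counts of called probe sets stayed within 1.5 times the reported count in 289 of 351 alternatives, being lower in 60 and higher in 2. Of 4546 repeats for 382 named results, 4381 kept direction and side of the threshold. Of 750 repeats for 51 list results, 674 did. The large tZ counts changed by more than that only with a 2-fold minimum, stricter by construction, while differences between times and time effects depended on other choices too. A list was counted as reversed if its median or camera's direction changed sign, a rule widened after the results. Signal near background limits dim genes such as DREB1G, OsCKX1, OsCKX3 and OsRR1, shrunk by the pseudocount. For the counts below other than those left with fewer arrays, a stricter threshold or a 2-fold minimum, the cause was not tested.

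With a 2-fold minimum the counts were 3889 for tZ in root at 30 min, 2853 for tZ in root at 120 min, 402 for the root difference between times, 208 for the root DMSO time effect, 378 for the root tZ time effect, 4519 for tZ in leaf at 30 min, 4023 for tZ in leaf at 120 min, 270 for the leaf difference between times, 26 for the leaf DMSO time effect, 348 for the leaf tZ time effect, 4753 for leaf minus root at 30 min, 4624 for leaf minus root at 120 min, 13613 for the organs, 157 for the DMSO time effect between organs and 332 for the tZ time effect between organs. At an adjusted p below 0.01 they were 531 for the root difference between times, 909 for the root DMSO time effect, 1046 for the root tZ time effect, 691 for the leaf difference between times, 136 for the leaf DMSO time effect, 1572 for the leaf tZ time effect, 281 for the DMSO time effect between organs and 604 for the tZ time effect between organs. With eBayes without a trend they were 403 for the root difference between times, 850 for the root DMSO time effect, 1232 for the root tZ time effect, 678 for the leaf difference between times, 61 for the leaf DMSO time effect, 1819 for the leaf tZ time effect and 499 for the DMSO time effect between organs. With all 24 arrays in 1 fit they were 2389 for the root difference between times, 723 for the leaf difference between times, 147 for the leaf DMSO time effect and 1705 for the leaf tZ time effect. With arrays shifted to 1 median they were 800 for the leaf difference between times and 141 for the leaf DMSO time effect. Without the filter the count was 315 for the leaf DMSO time effect, with array weights 1297 for the DMSO time effect between organs, and with only the arrays compared 797 for the tZ time effect between organs. Of lists in the planned comparisons, 38 were called at the preset correlation, 4 with an estimated correlation, 99 by fry and 16 by the first patterns. Calls shared by both correlations were type-A regulators in the root and leaf DMSO time effects and ribosomal proteins in leaf at 30 and 120 min.

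With 1 array left out, counts ran from 848 to 1819 for the root difference between times, with 957 without root DMSO 30 min replicate 1, 848 without root DMSO 30 min replicate 2, 1042 without root tZ 30 min replicate 2, 1010 without root tZ 30 min replicate 3, 985 without root DMSO 120 min replicate 2 and 1042 without root DMSO 120 min replicate 3. They ran from 1203 to 1703 for the root DMSO time effect, with 1362 without root DMSO 30 min replicate 1, 1203 without root DMSO 30 min replicate 2, 1351 without root DMSO 30 min replicate 3, 1357 without root DMSO 120 min replicate 2 and 1294 without root DMSO 120 min replicate 3, and this count was 3129 without root tZ 120 min replicate 2, which shares the fit. They ran from 1397 to 2136 for the root tZ time effect, with 1397 without root tZ 30 min replicate 2 and 1438 without root tZ 30 min replicate 3. They ran from 146 to 330 for the leaf DMSO time effect, with 285 without leaf DMSO 30 min replicate 1, 196 without leaf DMSO 30 min replicate 3, 240 without leaf DMSO 120 min replicate 1, 146 without leaf DMSO 120 min replicate 2 and 180 without leaf DMSO 120 min replicate 3. They ran from 502 to 1239 for the DMSO time effect between organs, with 553 without root DMSO 30 min replicate 2, 518 without leaf DMSO 30 min replicate 3, 527 without leaf DMSO 120 min replicate 2 and 502 without leaf DMSO 120 min replicate 3. The replicate numbers do not pair the arrays, since same-numbered arrays deviated from their group means with correlations of -0.055 to 0.075. With the number as a block the counts were 11505 and 10311 in root and 15392 and 14675 in leaf at 30 and 120 min, and 299 for the leaf DMSO time effect. The block changed the call of 8 of 382 named results and of 0 of 51 list results.

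Signs changed for uncalled values. In the cytokinin dehydrogenase list in root at 30 min the direction turned while the median was -0.62 with fry, -0.58 and -0.61 with quantile normalization of all arrays and within organs, and -0.71 to -0.32 with 1 array left out. The type-A median in root at 120 min was 0.028 with arrays shifted to the same median and -0.23 to 0.052 with 1 array left out. Other ranges with 1 array left out were -0.026 to 0.15 for the dehydrogenase list in the leaf DMSO time effect, -0.23 to 0.052 for OsRR2 in root at 120 min, -0.17 to 0.025 for OsRR9 in the root difference between times, -0.095 to 0.0024 for OsCASP1 in the root DMSO time effect, -0.026 to 0.15 for OsCKX11 and -0.26 to 0.063 for OsCKX5 in the leaf DMSO time effect, -0.18 to 0.034 for OsRR1 between the organs and -0.042 to 0.13 for OsCKX11 in the tZ time effect between organs. OsRR1 between the organs was 0.35 with quantile normalization of all arrays. Shifting arrays to the same median moved the median change of all probe sets by 0.11 in root at 120 min, 0.14 in the root difference, -0.17 between organs at 120 min, 0.40 for the organs and 0.11 for the DMSO time effect between organs, and quantile normalization of all arrays moved it by 0.20 for the organs.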

Other observations

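All comparisons in this part were added after the results had been seen. Under an exchange of the tZ 30 min and DMSO 120 min labels, those of tZ 120 min with tZ 30 min would compare tZ with DMSO at 120 min. In leaf, arrays labelled tZ 120 min differed from those labelled tZ 30 min in cytokinin genes. OsRR1 read 758 ± 102 against 32.5 ± 28.8, OsRR9 12423 ± 523 against 989.8 ± 48.6 and OsRR4 4139.9 ± 307 against 354 ± 40.6. OsCKX4 read 2941 ± 174 against 526 ± 46.8, and adjusted p for these 4 genes ran from 1.5e-15 to 1.3e-07. Type-A regulators had 5 of 5 members higher and 0 lower (5 and 0 adjusted over the list alone). For type-A regulators the median log2 change was 3.48 (camera adjusted p = 4.1e-18, and adjusted p = 3.9e-04 with an estimated correlation). Cytokinin dehydrogenases had 2 of 3 members higher and 0 lower (2 and 0 adjusted over the list alone). For cytokinin dehydrogenases the median log2 change was 1.73 (camera adjusted p = 4.2e-05, and adjusted p = 0.0194 with an estimated correlation). Jasmonate genes had 11 of 34 members higher and 2 lower (14 and 5 adjusted over the list alone). For jasmonate genes the median log2 change was 0.13 (camera adjusted p = 4.3e-04, and adjusted p = 0.0893 with an estimated correlation). Chlorophyll synthesis genes had 2 of 8 members higher and 0 lower (3 and 0 adjusted over the list alone). For chlorophyll synthesis genes the median log2 change was 0.21 (camera adjusted p = 0.0142, and adjusted p = 0.105 with an estimated correlation). OsTIFY11e read 3431 ± 176 against 1230.1 ± 157. Lower at 120 min were LEA19 at 139 ± 50.7 against 647 ± 109, OsCHS1 at 891 ± 84.0 against 3503 ± 281 and CDKE-1 at 1119.7 ± 35.2 against 3422 ± 543. In all 2749 of the 34316 probe sets tested changed at an adjusted p below 0.05 in limma, 1303 higher and 1446 lower. The share higher, 47.4%, became 51.8% with arrays shifted to the same median.

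In root the same comparison had OsRR9 at 10111 ± 1365 against 1298 ± 96.3 and OsCKX5 at 2966 ± 663 against 451 ± 22.0. The brassinosteroid synthesis gene OsCYP85A1 read 1410 ± 186 against 241 ± 52.6, and adjusted p for these 3 genes ran from 8.5e-11 to 1.2e-07. Type-A regulators had 5 of 5 members higher and 0 lower (5 and 0 adjusted over the list alone). For type-A regulators the median log2 change was 1.55 (camera adjusted p = 2.8e-13, and adjusted p = 0.0538 with an estimated correlation). Cytokinin dehydrogenases had 4 of 5 members higher and 0 lower (4 and 0 adjusted over the list alone). For cytokinin dehydrogenases the median log2 change was 1.96 (camera adjusted p = 6.2e-07, and adjusted p = 0.0768 with an estimated correlation). Lower at 120 min were OsPIN4 at 126 ± 14.9 against 398 ± 90.2 and OsCASPL1C1 at 2303 ± 205 against 4882 ± 158. In all 2312 of the 34316 probe sets tested changed at an adjusted p below 0.05 in limma, 1252 higher and 1060 lower. The count was 1397 and 1438 without replicate 2 or 3 of tZ 30 min. The share higher, 54.2%, became 69.6% with arrays shifted to the same median. The time effects in DMSO and tZ correlated across probe sets at a Pearson r of 0.0735 in root and 0.0809 in leaf. The calls nevertheless overlapped. In root 263 were higher and 185 lower in both, where independence gives 40.6 and 31.6, and 127 had opposite signs. In leaf 102 were higher and 84 lower in both, where independence gives 9.23 and 10.0, and 47 had opposite signs.

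The groups labelled DMSO 30 min and tZ 120 min keep their treatment and time whether or not the labels of the other groups were exchanged, although this comparison mixes treatment with time. In root, tZ 120 min against DMSO 30 min gave 10088 called probe sets, 4023 higher and 6065 lower, and all 5 type-A regulators were higher with a median log2 change of 2.43. Replicate 2 of root tZ 120 min, which lay between these groups, is among the arrays, and without it the count was 10612, 4308 higher and 6304 lower, with all 5 regulators higher and a median of 2.59. In leaf it gave 15652, 8020 higher and 7632 lower, with all 5 higher and a median of 2.74.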
